A study of Mus musculus with 14 samples.

How the data were processed

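Gene expression was measured by RNA sequencing in 14 mouse lung libraries. Per the labels, the mice were of the C57BL/6 strain, and mRNA was enriched with oligo-dT beads from RNeasy-purified RNA and made into libraries with the NEBNext Ultra II kit. Per the submitters' processing notes, reads passed through FastQC 0.11.8 and Trim Galore 0.6.6, the tools also included STAR 2.7.5b and Salmon 1.2.1, and the genome build was GRCm38. The release of the annotation and the strand setting of the counting were not given in the sources used here. The deposited tables held 1 estimated count per gene and library, as Salmon gives. There were 3 tables, 1 per experiment, each with the same 54347 genes, and 24.2% of the values were not whole numbers. All gene symbols came from the tables, 105 symbols occurred more than once, and of the gene identifiers 53307 matched GENCODE M21 in the same version and 54094 in any version. Positions were taken from that annotation of GRCm38 by identifier.

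Estimated counts were rounded to whole numbers before testing. Total counts per library were 18198872 to 24393000, so a floor of 3 counts per library corresponds to about 0.136 CPM (counts per 1e+06 counts) in the intrathecal libraries. Floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Replicates were compared pairwise: chi-square per degree of freedom was 9.57 to 23.1 and Pearson's r across genes 0.989 to 0.994, so each library was counted as a separate sample. Group means are CPM after scaling by TMM factors, and values per library are CPM of the total count.

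Each experiment was fitted alone with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, a robust quasi-likelihood fit, and the quasi-likelihood F test. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. The difference between the 2 RTX effects was tested as a contrast in 1 fit of 10 libraries, and that between the subcutaneous RTX effect and the recipient effect in 1 fit of 9 libraries. Gene lists were tested with camera of limma 3.58.1 on voom values of the same genes, with the correlation between genes preset at 0.01, and beside it with an estimated correlation and with fry. Adjusted p-values of lists are Benjamini-Hochberg values over the 38 lists. The 38 lists held cell types of the lung, of neighbouring tissues and of blood, type 2 and inflammatory mediators, JAK-STAT and interferon targets, and signs of RNA quality or handling, and a further list of sex-linked genes entered no set test. The lists, tests and rule for naming genes were fixed before the data were examined.

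The rule named, per comparison, up to 8 genes with the largest rise and 8 with the largest fall among genes past the threshold whose groups did not overlap, with a mean log2 CPM of at least 1 and no predicted-gene or clone name. It also named up to 4 members past the threshold of each list past the threshold, or the 2 with the smallest p where none passed, and 14 fixed genes (Jak1, Il4, Il5, Il13, Il33, Ccl11, Ccl24, Retnla, Arg1, Chil3, Muc5ac, Clca1, Calca and Calcb). For the difference between the RTX effects it named up to 5 genes per direction.

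The alternatives were DESeq2 size factors, total counts alone, no low-count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma voom, no robust prior, all 14 libraries in 1 fit, the replicate number as a block, an adjusted p of 0.1, and leaving out each library in turn. After the data had been examined, a fit of all 14 libraries with library state as a term was added. The state was set from 2 transcripts: state A had over 2 CPM of Rps3a2, state B at most 2 CPM of Rps3a2 and over 2 CPM of Hmga2, and state C neither.

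The procedure was tested on simulated counts with 200 changed genes. For the chimera comparison (17014 genes tested) 70 of 98 changes of 2-fold and 92 of 97 of 4-fold were recovered, with 27 false calls. For the intrathecal comparison (17071 genes tested) 70 of 98 and 92 of 98 were recovered, with 24 false calls, and for the subcutaneous comparison (17061 genes tested) 68 of 100 and 81 of 95, with 25 false calls. In each of these 3 simulations the share of false calls among the calls was above the threshold of 0.05. A list shifted by 0.5 log2 was found with the preset correlation in each comparison, at an adjusted p of 5.31e-14 for the chimera comparison, 9.27e-18 for the intrathecal and 1.17e-14 for the subcutaneous one. Of the lists that were not shifted, 1, 3 and 1 were also called with the preset correlation in these comparisons, and on counts with no change 9, 3 and 1 genes were called. With an estimated correlation the shifted list was missed in these 3 comparisons, at adjusted p = 0.723, 0.152 and 0.116. Each gene was drawn independently, so the simulations could not show how often lists of genes that vary together are called without a shift. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No deposited column of per-sample values was left out. Results on items withheld for evaluation are not reported here.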

Results

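RNA from 14 lung libraries was profiled after intranasal Alternaria alternata, a fungal allergen extract given at 2 mg per dose in 40 µl on 4 consecutive days to induce allergic lung inflammation. The libraries formed 3 experiments, each with its own controls. In the first, irradiated recipients that were wild type (WT, n = 2) or carried a human JAK1 gain of function (GOF, n = 2) received 1e+07 live WT bone marrow cells. JAK1 is a tyrosine kinase that relays signals of cytokine receptors. In the second, spinal visceral afferents were ablated with intrathecal resiniferatoxin (RTX, n = 3), a TRPV1 agonist that destroys sensory neurons bearing this channel, at 25 ng per mouse and day for 2 days, against 10 µl saline (n = 2). In the third, both vagal and spinal visceral afferents were ablated with subcutaneous RTX at 30, 70 and 100 µg/kg over 3 days (n = 3), against 100 µl saline (n = 2). Libraries held 18198872 to 24393000 counts, with 23441 to 24413 genes counted at least once. The labels do not say that the libraries came from separate mice, so p-values measure the spread between these samples, which may be technical.

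The chimera experiment asked how JAK1 GOF outside the transplanted marrow changed the allergen-exposed lung. In JAK1 GOF recipients, 5 of 20 genes of B and plasma cells, 6 of 18 of T cells and 4 of 17 of type 2 lymphocytes fell, and 6 of 16 of heart muscle rose. None of these 4 lists passed with camera at an estimated correlation (adjusted p = 0.437 with an estimated correlation). Chil3, a chitinase-like protein of alternatively activated macrophages, fell from 1380 ± 428 CPM to 361 ± 7.86 CPM (SD, n = 2 and 2), and Igkc, the kappa light chain constant region, from 144 ± 5.77 to 64.1 ± 1.91 CPM. Il7r and Il2ra, receptor chains for interleukin 7 and interleukin 2, fell by 1.09 and 1.33 on the log2 scale, the scale of all gene and list values given without CPM. Bpifa1, a secreted airway protein, rose from 109 ± 11.1 to 322 ± 21.4 CPM, and Tnnt2, cardiac troponin T, from 44.5 ± 7.23 to 95.1 ± 10.7 CPM.

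edgeR called 124 of 17298 genes at an adjusted p under 0.05, 30 higher and 94 lower, and 8 of them had a predicted-gene or clone name. An unadjusted p under 0.05 was reached by 2001 genes, 801 higher and 1200 lower, and the groups did not overlap in 7439 genes (43.0%, where chance gives 33.3%). DESeq2 called 290 genes and limma voom 87. The count was 919 without WT recipient 1, 303 without WT recipient 2, 83 without GOF recipient 1 and 93 without GOF recipient 2, and 122, 103, 42 and 54 of the 124 genes remained; each of these fits had 1 library left in 1 group. Of 47 genes past the threshold that were followed through each alternative, 10 of them picked after the values were seen, 19 kept the call whichever library was left out. Among these were Chil3, Igkc, Jchain, Il7r, Il2ra, Ccl8, Itgae, Bpifa1, Tnnt2, Pln and Myl7. WT recipient 1 differed from the other 3 libraries of the experiment in a set of trace transcripts described with the intrathecal experiment, so the 919 calls without it came from libraries of 1 state. A fit of all 14 libraries called 50 genes and kept 28 of the 124, and with library state as a term in it 177 genes were called (15 higher, 162 lower) and 50 of the 124 kept.

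The mouse Jak1 gene (GRCm38 chromosome 4, 101152367 to 101265282, minus strand) was at 256 and 281 CPM in WT recipients and at 204 and 191 CPM in GOF recipients. Its log2 fold change was −0.43 ± 0.13 (SE; edgeR adjusted p = 0.206). Counts of the mouse gene do not identify the human sequence, so they do not check the genotype label. The JAK-STAT feedback list had a median log2 fold change of −0.19, with 0 of 17 members past the threshold over all genes and 3 lower when adjusted over the list alone (camera adjusted p = 0.0017; adjusted p = 0.497 with an estimated correlation). Its members with the smallest p were Jak2 at −0.52 and Stat5a at −0.53 (edgeR adjusted p = 0.0998 and 0.152). The interferon response list had a median of −0.16 with 0 of 26 past the threshold either way (camera adjusted p = 0.0257; adjusted p = 0.567 with an estimated correlation), and Bst2 at 0.38 and Cxcl9 at −1.50 did not pass (edgeR adjusted p = 0.256 and 0.278).

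In the T cell list all 18 members were negative, 6 fell over all genes and 14 when adjusted over the list alone, with a median of −0.83 (camera adjusted p = 1.87e-14; adjusted p = 0.437 with an estimated correlation). Cd4, Cd6, Ctla4 and Foxp3, the last 2 being marks of regulatory T cells, fell by 0.89, 1.03, 1.25 and 1.31. In the B and plasma cell list 5 of 20 members fell over all genes and 12 when adjusted over the list alone, with a median of −0.74 (camera adjusted p = 5.07e-16; adjusted p = 0.437 with an estimated correlation). Jchain, the chain that joins secreted IgM and IgA, fell by 1.32, Igha by 1.28 and Ighg2b by 1.74. Of the 8 largest falls under the naming rule, 4 were in immunoglobulin genes: Ighv8-12 fell by 3.00, Ighg2c by 2.43, Ighv2-2 by 2.41 and Ighv1-64 by 2.18, although reads of such related genes can be shared among them. The type 2 lymphocyte list had 4 of 17 members lower over all genes and 8 when adjusted over the list alone, with a median of −0.81 (camera adjusted p = 2.11e-07; adjusted p = 0.437 with an estimated correlation). Its members that fell were Il7r, Il2ra, Il1rl1, a receptor chain for interleukin 33, by 1.39, and Icos by 0.85. The calls of Il1rl1, Icos, Ctla4, Cd6, Igha and Ighg2b ended without GOF recipient 1 and also without GOF recipient 2, those of Cd4 without GOF recipient 1 and those of Foxp3 and Ighv1-64 without GOF recipient 2. The natural killer list had a median of −0.67 with 0 of 13 past the threshold and 1 lower when adjusted over the list alone (camera adjusted p = 3.64e-05; adjusted p = 0.449 with an estimated correlation). Klrk1 was at −1.07 and Klrd1 at −0.83 (edgeR adjusted p = 0.0663 and 0.282). Xist (−0.89) and heart muscle genes (median 1.06) differed between the same libraries.

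The list of alternatively activated macrophages had 2 of 17 members lower over all genes (Chil3 and Ccl22) and 8 when adjusted over the list alone, with a median of −0.92 (camera adjusted p = 7.12e-09; adjusted p = 0.437 with an estimated correlation). Type 2 chemokines had 3 of 9 lower over all genes and 4 when adjusted over the list alone. Their median ratio of GOF to WT recipients was 0.499 on the linear scale, a fall (camera adjusted p = 2.83e-06, and adjusted p = 0.449 with an estimated correlation). Ccl8, Ccl9 and Ccl22, attractants of leukocytes, fell by 1.00, 0.83 and 1.26, and the calls of Ccl9 and Ccl22 ended without GOF recipient 1 and also without GOF recipient 2. The dendritic cell list had 3 of 14 lower over all genes and 9 when adjusted over the list alone, with a median of −0.64 (camera adjusted p = 5.48e-08; adjusted p = 0.437 with an estimated correlation). Itgae, the integrin of conventional dendritic cells and resident T cells, fell by 1.29 and Flt3 by 1.21, the latter not called without GOF recipient 2. In the antigen presentation list 0 of 11 members passed over all genes and all 11 were lower when adjusted over the list alone, with a median of −0.71 (camera adjusted p = 1.07e-10; adjusted p = 0.437 with an estimated correlation). H2-DMa was at −0.65 and H2-Ob at −0.71 (edgeR adjusted p = 0.122 and 0.124). The eosinophil list had 0 of 11 past the threshold and 6 lower when adjusted over the list alone, with a median of −0.95 (camera adjusted p = 4.56e-05; adjusted p = 0.449 with an estimated correlation). Prg2 was at −3.70 and Ear2 at −0.96 (edgeR adjusted p = 0.0594 and 0.175). The neutrophil list had 1 of 13 lower over all genes, Retnlg by 1.21, and 1 higher and 3 lower when adjusted over the list alone, with a median of −0.39 (camera adjusted p = 0.000192; adjusted p = 0.497 with an estimated correlation). Inflammatory cytokines had a median of −0.39 with 0 of 16 past the threshold and 2 lower when adjusted over the list alone (camera adjusted p = 0.0257; adjusted p = 0.567 with an estimated correlation). Il1b was at −0.64 and Ptgs2 at −0.56 (edgeR adjusted p = 0.0981 and 0.119). The proliferation list had a median of −0.43 with 0 of 20 past the threshold either way (camera adjusted p = 3.64e-05; adjusted p = 0.515 with an estimated correlation). Mki67 was at −0.64 and Rrm2 at −0.64. Monocytes and interstitial macrophages, alveolar macrophages, and mast cells and basophils did not pass, with medians of −0.14, −0.05 and 0.13 (camera adjusted p = 0.197, 0.345 and 0.397). These values, too, were set beside an Xist difference of −0.89 between the groups.

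Mucus genes had lower values that did not pass. In the goblet cell list Bpifa1 rose and 0 members fell over all genes, with 1 higher and 5 of 13 lower when adjusted over the list alone and a median of −0.73 (camera adjusted p = 8.60e-07; adjusted p = 0.474 with an estimated correlation). Muc5ac, the main inducible airway mucin, was at 103 ± 43.9 CPM in WT recipients and 13.0 ± 0.352 CPM in GOF recipients (edgeR adjusted p = 0.0587), and Clca1, a secreted protein of goblet cells, at 587 ± 204 and 62.5 ± 24.6 CPM (edgeR adjusted p = 0.0686). Of the other fixed genes, Arg1 had a log2 fold change of −1.75 ± 0.37, Ccl11 −1.53 ± 0.51, Ccl24 −2.33 ± 1.03, Retnla −0.67 ± 0.32 and Il33 −0.41 ± 0.42, none past the threshold (edgeR adjusted p = 0.215, 0.398, 0.580, 0.490 and 0.791). Calca and Calcb, which encode the neuropeptide CGRP, were at 0.17 ± 0.36 and 0.22 ± 0.52. Il4, Il5 and Il13 had too few counts to be tested, with means of 0.502, 0.310 and 0.765 CPM in WT recipients and 0.144, 0.210 and 0.284 CPM in GOF recipients. The same 4 libraries differed in Xist by −0.89.

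Tissue lists with positive medians included heart muscle, fat and epithelium. The heart muscle list had 6 of 16 members higher over all genes and 10 when adjusted over the list alone, with a median of 1.06 (camera adjusted p = 2.45e-16; adjusted p = 0.437 with an estimated correlation). Sln, Myl7 and Pln, atrial or sarcoplasmic reticulum proteins of heart muscle, rose by 1.51, 1.36 and 1.34, as did Csrp3 by 1.38 and Mybphl by 1.55, and the calls of Sln, Csrp3 and Mybphl ended without GOF recipient 1. Eef1a2, an elongation factor of muscle and neurons, rose by 1.30, Krt15, a keratin of basal cells, by 1.78, and Fer1l6, H2-M2 and Gpr141b fell by 2.38, 2.03 and 1.75. Krt15 and H2-M2 were not called without GOF recipient 1, and Eef1a2 and Gpr141b without GOF recipient 1 and also without GOF recipient 2. The fat list had 0 of 8 past the threshold and 4 higher when adjusted over the list alone, with a median of 1.42 (camera adjusted p = 5.48e-08; adjusted p = 0.437 with an estimated correlation). Pck1 was at 1.37 and Adrb3 at 0.75. Club cells had a median of 0.41 with 2 of 11 higher when adjusted over the list alone (camera adjusted p = 0.000171; adjusted p = 0.437 with an estimated correlation), ciliated cells 0.25 with 5 of 15 (camera adjusted p = 0.000571; adjusted p = 0.437 with an estimated correlation), endothelium 0.17 with 2 of 18 (camera adjusted p = 4.88e-05; adjusted p = 0.449 with an estimated correlation) and mesothelium 0.20 with 2 of 8 (camera adjusted p = 0.00256; adjusted p = 0.437 with an estimated correlation), and 0 members of these 4 lists passed over all genes. Scgb3a2 and Scgb3a1 were at 0.73 and 0.62, Foxj1 and Dynlrb2 at 0.52 and 0.63, Apln and Plvap at 0.52 and 0.56, and Upk3b and Wt1 at 0.48 and 0.75. Alveolar type 1 cells had a median of 0.09 (camera adjusted p = 0.0290; adjusted p = 0.497 with an estimated correlation) and the neural, glial and neuroendocrine list 0.38 (camera adjusted p = 0.0290; adjusted p = 0.437 with an estimated correlation), both with 0 members past the threshold either way. Aqp5 and Rtkn2 were at 0.35 and 0.28, and Uchl1 at 0.62. Xist differed by −0.89 between these groups.

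Lists on handling and time of day also moved in this comparison. Heat shock genes had a median of 0.41 with all 10 positive, 0 past the threshold and 1 higher when adjusted over the list alone (camera adjusted p = 8.81e-07; adjusted p = 0.449 with an estimated correlation). Hspb1 was at 0.61 and Dnajb1 at 0.54. Immediate early genes had a median of −0.32 with 0 of 16 past the threshold either way (camera adjusted p = 0.0209; adjusted p = 0.483 with an estimated correlation). Egr3 was at −0.79 and Egr1 at −0.46. In the circadian clock list 2 of 13 members rose over all genes, and 6 were higher and 1 lower when adjusted over the list alone, with a median of 0.32 (camera adjusted p = 0.000183; adjusted p = 0.437 with an estimated correlation). Dbp, a clock output factor, and Nr1d1, a clock repressor, rose by 0.88 and 0.93. Both calls ended without GOF recipient 1, and that of Dbp also without GOF recipient 2. Xist, the RNA of the inactive X chromosome, was looked at after the values were seen. It differed with the groups as well, at 122 and 132 CPM in WT recipients and 62.9 and 73.2 CPM in GOF recipients (log2 fold change −0.89 ± 0.13; edgeR adjusted p = 0.0158), and was at most 5.12 CPM in the other 10 libraries. The Y-linked gene Ddx3y was at 57.6 to 74.6 CPM in all 4 chimera libraries, while Eif2s3y was at 18.1 CPM in GOF recipient 1 and at 48.3 to 60.3 CPM in the other 3. The immune lists that passed at the preset correlation therefore moved together with heart muscle genes and with Xist. Those of monocytes and interstitial macrophages, alveolar macrophages, and mast cells and basophils did not pass.

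**Figure D1:**
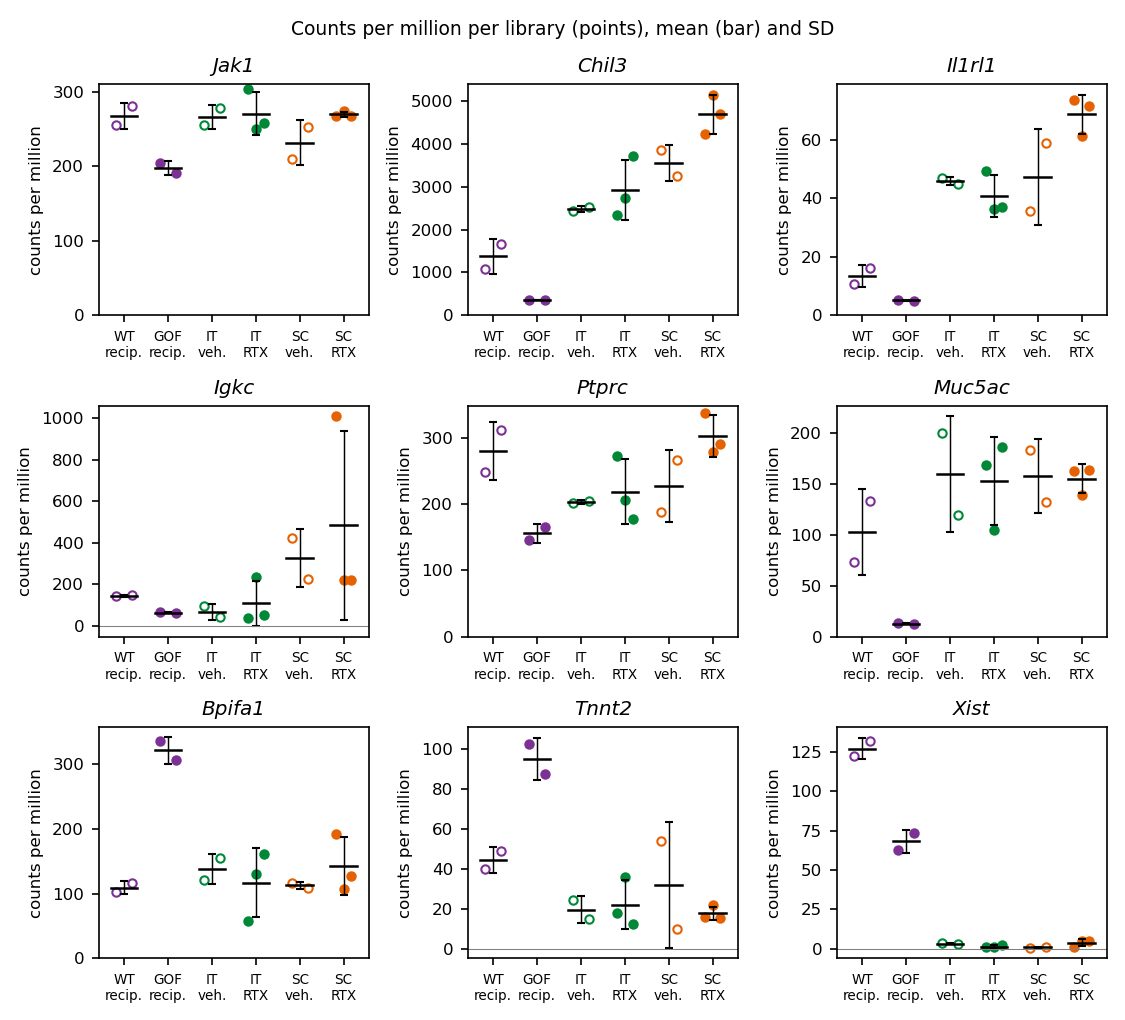
Expression (CPM) of 9 genes in each of the 14 libraries (points), with the group mean (bar) and SD (whisker); WT recip. and GOF recip. are the chimera groups, IT and SC the intrathecal and subcutaneous experiments. Chil3, Il1rl1, Igkc, Ptprc, Muc5ac and Xist were lower, and Bpifa1 and Tnnt2 higher, in both GOF recipients than in both WT recipients.

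The intrathecal experiment asked what loss of spinal afferents changed in the allergen-exposed lung. Genes of protein folding differed in both directions between vehicle and RTX libraries. Hspb1, a small heat shock protein, rose from 142 ± 15.2 to 538 ± 59.9 CPM (SD, n = 2 and 3) and Hspe1, a mitochondrial chaperonin, from 68.1 ± 1.84 to 127 ± 6.34 CPM. Hspa1b, an inducible HSP70, fell from 409 ± 95.6 to 68.3 ± 17.8 CPM and Dnajb1, its cochaperone, by 1.21. All vehicle libraries were of state A and all RTX libraries of state B, so RTX and library state were not separated. Cebpb, a transcription factor of inflammation, rose from 42.6 ± 0.612 to 92.3 ± 3.81 CPM. The type 2 cytokine genes were at like levels in both groups, with Il5 at 4.40 ± 1.18 CPM after vehicle and 5.15 ± 0.409 after RTX and Il13 at 7.38 ± 1.95 and 7.35 ± 0.481 (log2 fold changes 0.23 ± 0.22 and −0.00 ± 0.19).

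edgeR called 54 of 17360 genes, 19 higher and 35 lower. An unadjusted p under 0.05 was reached by 1993 genes, 1016 higher and 977 lower, and the groups did not overlap in 5255 genes (30.3%, where chance gives 20%). DESeq2 called 243 genes and limma voom 58. The count was 19 without RTX replicate 2, 32 without vehicle replicate 1 and 33 without RTX replicate 3, and 16, 23 and 26 of the 54 genes remained. Of 29 genes past the threshold that were followed through each alternative, 13 of them picked after the values were seen, 12 kept the call whichever library was left out. These were Hspb1, Hspe1, Cebpb, Dnaja1, Chordc1, Herpud1, Arhgef25, Lrrc17, Ccl21b, Ccl21d, Prl2c2 and Rpl3-ps1. Prl2c2 and Rpl3-ps1 belong to the trace transcripts described next, so a call kept in this way does not separate RTX from library state. Hspe1, Dnajb1, Dnaja1, Chordc1 and Herpud1 lay outside the naming rule and were chosen after the values were seen.

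A set of trace transcripts separated libraries within and across the experiments, in a way that coincided with RTX in the intrathecal one. Rps3a2 exceeded 2 CPM in both intrathecal vehicle libraries, in WT recipient 1 and in subcutaneous RTX replicates 2 and 3 (state A). Hmga2 exceeded 2 CPM, without Rps3a2, in the 3 intrathecal RTX libraries, WT recipient 2, both GOF recipients and subcutaneous vehicle replicate 1 (state B). Neither did in subcutaneous vehicle replicate 2 and RTX replicate 1 (state C). Ptn, a growth factor, was at 42.5 and 24.7 CPM in the intrathecal vehicle libraries and 2.54 to 4.14 CPM in the RTX libraries, but also at 22.4 CPM in WT recipient 1 and 2.39 CPM in WT recipient 2. A fit of all 14 libraries without state called 7 genes for intrathecal RTX by edgeR, all among the 54, so most calls were lost by pooling alone. With state as a term in that fit 5 genes were called, all lower, and 4 of the 54 remained. Those kept were Dnaja1, Chordc1, Hspa1b and Dnajb1, and Bhlha15 was added. Hspb1 and Hspe1, which rose, were no longer called.

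Several of the largest changes under the naming rule belonged to these trace transcripts. Ptn fell by 3.32, H19 by 3.01, and Cdkn2a by 1.88, and the ribosomal pseudogene Rpl3-ps1 had a log2 fold change of −5.28. Hmga2, Prl2c2 and Megf10 rose by 3.54, 3.42 and 1.86. With the state term Ptn was at 0.14, Cdkn2a at 0.45 and Megf10 at −0.22, signs opposite to those without it. The call of Cdkn2a ended without any 1 library, and that of Megf10 in each case but without RTX replicate 1. That of H19 ended without either vehicle replicate or RTX replicate 2, that of Hmga2 without RTX replicate 2 and that of Ptn without RTX replicate 3. Ccl21d and Ccl21b, near-identical copies of a lymphoid chemokine gene on chromosome 4, exchanged places: Ccl21d was at 0 in both vehicle libraries and at least 244-fold higher after RTX, and Ccl21b at 0 in the 3 RTX libraries and at least 223-fold lower, both against a floor of 3 counts per library. Their sum was 30.3 ± 9.96 CPM after vehicle and 33.2 ± 4.8 CPM after RTX, and reads of near-identical copies can be assigned to either.

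In the heat shock list 2 of 10 members rose and 3 fell over all genes, and 4 were higher and 5 lower when adjusted over the list alone; the median was −0.27 and camera found no shift in 1 direction (adjusted p = 0.367). Hspa1b has a near-identical neighbour, Hspa1a, which was at 247 ± 104 CPM after vehicle and 33.0 ± 4.12 after RTX (edgeR adjusted p = 0.0558). Without the low-count filter Hspa1b was not called, nor without either vehicle replicate or RTX replicate 2, and Dnajb1 was not called without any 1 of the 3 RTX libraries. With library state as a term the log2 fold changes were 1.70 ± 0.27 for Hspb1, 0.48 ± 0.18 for Hspe1, −1.79 ± 0.23 for Dnajb1 and −3.76 ± 0.37 for Hspa1b, and edgeR adjusted p-values were 0.130, 1, 0.0230 and 0.0179. The fit of all 14 libraries without the term called Hspb1 but not Hspe1, Dnajb1 or Hspa1b. Derl3, of protein export from the endoplasmic reticulum, rose by 1.12 and the RNA of RNase P, Rpph1, by 1.02, and Lrrc17 and Tenm3 fell by 1.79 and 1.53. The calls of Derl3 and Tenm3 ended without any 1 library, and that of Rpph1 ended in each case but without RTX replicate 3.

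**Figure D2:**
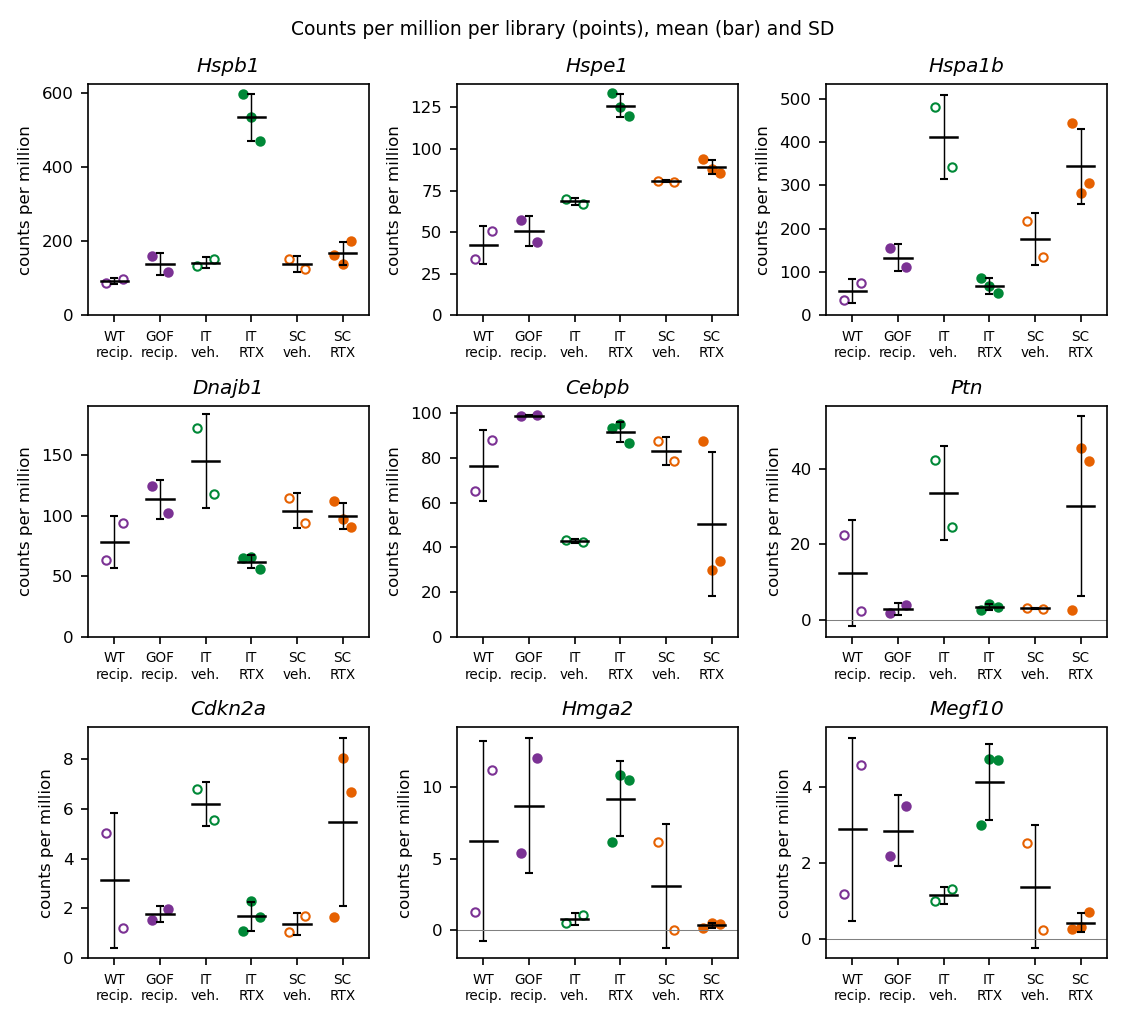
Expression (CPM) of 9 genes in each of the 14 libraries (points), with the group mean (bar) and SD (whisker). Hspb1 was highest in the 3 intrathecal RTX libraries, while Ptn and Cdkn2a were high and Hmga2 low in both intrathecal vehicle libraries and also in WT recipient 1 and subcutaneous RTX replicates 2 and 3.

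Of the 38 lists, 5 passed with the preset correlation after intrathecal RTX, none of them with a member past the threshold over all genes. Inflammatory cytokines had a median of 0.36 with 3 of 15 members higher when adjusted over the list alone (camera adjusted p = 0.00241; adjusted p = 0.904 with an estimated correlation). Il1b was at 15.6 ± 2.18 CPM after vehicle and 25.1 ± 0.815 after RTX, and Cxcl3, a neutrophil attractant, at 3.86 ± 1.25 and 7.80 ± 1.36 (edgeR adjusted p = 0.0507 and 0.148). T cells had a median of 0.35 with 2 of 18 higher when adjusted over the list alone (camera adjusted p = 0.00419; adjusted p = 0.904 with an estimated correlation). Ctla4 was at 0.77 and Cd3d at 0.86. Type 2 chemokines had a median of 0.23 with 4 of 10 higher when adjusted over the list alone (camera adjusted p = 0.00528; adjusted p = 0.904 with an estimated correlation). Ccl24, an attractant of eosinophils, was at 149 ± 27.3 and 245 ± 26.3 CPM (edgeR adjusted p = 0.0734) and Ccl7 at 0.57. Mesothelium had a median of −0.21 with 2 of 8 lower when adjusted over the list alone (camera adjusted p = 0.00419; adjusted p = 0.904 with an estimated correlation). Gpm6a was at −0.50 and Muc16 at −0.61. Alveolar type 1 cells had a median of −0.16 with 1 of 12 lower (camera adjusted p = 0.00528; adjusted p = 0.904 with an estimated correlation). Sec14l3 was at −0.42 and Emp2 at −0.20. Leaving out 1 library moved the number of lists from 5 to between 8, without RTX replicate 1, and 15, without vehicle replicate 1. Il33, the epithelial alarmin, was at 467 ± 26.2 CPM after vehicle and 669 ± 134 after RTX (log2 fold change 0.52 ± 0.15; edgeR adjusted p = 0.266). Arg1, Chil3, Retnla and Ccl11 were at 0.43 ± 0.27, 0.26 ± 0.19, 0.30 ± 0.11 and 0.19 ± 0.08, and Muc5ac, Clca1, Il4, Jak1, Calca and Calcb between −0.32 (Calcb) and 0.14 (Il4), none past the threshold.

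The subcutaneous experiment asked what loss of both vagal and spinal afferents changed. After RTX, list medians were lower for ciliated, club and alveolar type 1 cells and higher for B cells, eosinophils and dividing cells. No single gene passed the threshold with edgeR or limma voom, while DESeq2 called 683. None of these lists passed with camera at an estimated correlation (adjusted p = 0.551 with an estimated correlation). Scgb1a1, the main secretory protein of club cells, was at 9005 ± 2760 CPM after vehicle and 4303 ± 293 after RTX (SD, n = 2 and 3), and Hopx, of alveolar type 1 cells, at 638 ± 87.8 and 394 ± 26.8. Cr2, the complement receptor of B cells, was at 2.93 ± 0.230 and 6.83 ± 0.644 CPM, and Mki67, a mark of dividing cells, at 126 ± 17.6 and 184 ± 10.5.

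edgeR called 0 of 17363 genes, with a smallest adjusted p of 0.0947, and an unadjusted p under 0.05 was reached by 3153 genes, 1557 higher and 1596 lower. DESeq2 called 683 genes, 349 higher and 334 lower, and limma voom 0. The groups did not overlap in 6629 genes (38.2%, where chance gives 20%). The edgeR count was 871 without vehicle replicate 2 (422 higher, 449 lower), where 1 vehicle library was left and the RTX libraries alone gave the spread, and 12 without RTX replicate 1, 2 without RTX replicate 2, 1 without vehicle replicate 1 and 0 without RTX replicate 3. In several genes vehicle replicate 2 was nearer to the RTX libraries than to vehicle replicate 1: Arg1 was at 411 CPM there, 122 CPM in vehicle replicate 1 and 443 to 660 CPM after RTX, and Ccl24 at 387, 142 and 323 to 452 CPM. The counts do not check the label of vehicle replicate 2, and if that label were wrong the subcutaneous values would have another meaning. A fit of all 14 libraries called 71 genes by edgeR, and 184 with library state as a term. The vehicle libraries were of states B and C and the RTX libraries of states A and C, as described with the intrathecal experiment. RTX was therefore only partly separated from library state.

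Of the 38 lists, 20 passed with the preset correlation, 13 higher and 7 lower, all with 0 members past the threshold over all genes, and without vehicle replicate 1 only 11 of the 20 were kept. Ciliated cells had a median of −0.67 with all 15 members negative and 12 lower when adjusted over the list alone (camera adjusted p = 4.46e-08; adjusted p = 0.551 with an estimated correlation). Tppp3 was at −0.88 ± 0.11 and Cfap126 at −0.78. Club cells had a median of −0.93 with 7 of 11 lower when adjusted over the list alone (camera adjusted p = 9.27e-08; adjusted p = 0.551 with an estimated correlation). Scgb1a1 was at −1.07 and Cldn10 at −0.93. Alveolar type 1 cells had a median of −0.48 with 10 of 12 lower when adjusted over the list alone (camera adjusted p = 1.17e-10; adjusted p = 0.551 with an estimated correlation). Hopx was at −0.69 and Aqp5 at −0.47. Endothelium had a median of −0.14 with 3 of 18 lower (camera adjusted p = 0.0121; adjusted p = 0.627 with an estimated correlation). Cldn5 was at −0.41 and Gpihbp1 at −0.61. The neural, glial and neuroendocrine list had a median of −0.64 with 0 of 9 past the threshold either way (camera adjusted p = 0.0255; adjusted p = 0.551 with an estimated correlation). Calca was at 4.22 ± 1.22 CPM after vehicle and 2.56 ± 0.0896 after RTX (log2 fold change −0.72 ± 0.25; edgeR adjusted p = 0.208), and Uchl1 at −0.40. The heart muscle list had all 15 members negative and a median of −0.77, with 0 past the threshold either way (camera adjusted p = 0.0593). Tnnt2 was at 32.1 ± 31.4 and 17.7 ± 3.49 CPM. The vehicle libraries differed in such genes: Myh6 was at 145 CPM in vehicle replicate 1 and 18.2 CPM in vehicle replicate 2. The RTX libraries lay between, at 40.6 to 63.7 CPM, so the direction for Myh6 rested on vehicle replicate 1.

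Leukocyte lists were on the higher side. B and plasma cells had a median of 1.01 with 13 of 20 higher when adjusted over the list alone (camera adjusted p = 9.27e-08; adjusted p = 0.551 with an estimated correlation). Cr2 was at 1.22 ± 0.20 and Fcer2a at 0.63. Proliferation genes had a median of 0.32 with all 20 positive and 10 higher when adjusted over the list alone (camera adjusted p = 1.50e-09; adjusted p = 0.551 with an estimated correlation). Cenpf was at 0.68 and Mki67 at 0.54. Eosinophils had a median of 0.90 with 6 of 13 higher (camera adjusted p = 6.87e-06; adjusted p = 0.551 with an estimated correlation). Siglecf was at 0.78 and Epx, the eosinophil peroxidase, at 1.98 (0.390 ± 0.295 CPM after vehicle and 1.54 ± 0.378 CPM after RTX). Neutrophils had a median of 0.71 with 4 of 12 higher (camera adjusted p = 0.000226; adjusted p = 0.551 with an estimated correlation). Mmp8 was at 0.92 and Retnlg at 0.88. Inflammatory cytokines had a median of 0.43 with 1 of 15 higher (camera adjusted p = 0.00498; adjusted p = 0.551 with an estimated correlation). Ccl4 was at 1.52 and Tnf at 0.91. Mast cells and basophils had a median of 0.71 with 0 of 14 (camera adjusted p = 0.00807; adjusted p = 0.551 with an estimated correlation). Mcpt1 was at 2.20 and Cma1 at 1.23. Monocytes and interstitial macrophages had a median of 0.22 with 1 of 16 (camera adjusted p = 0.00434; adjusted p = 0.551 with an estimated correlation). Spp1 was at 0.63 and Ms4a7 at 0.68. Antigen presentation had 0.20 with 1 of 11 (camera adjusted p = 0.00338; adjusted p = 0.551 with an estimated correlation). H2-Ob was at 0.74 and Ctss at 0.33. These counts of members are adjusted over the list alone.

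Alternatively activated macrophages had a median of 0.10 with 2 of 17 higher when adjusted over the list alone (camera adjusted p = 0.0146; adjusted p = 0.551 with an estimated correlation), type 2 lymphocytes 0.23 with 2 of 21 (camera adjusted p = 0.0202; adjusted p = 0.627 with an estimated correlation) and type 2 chemokines 0.28 with 2 of 10 (camera adjusted p = 0.0490; adjusted p = 0.551 with an estimated correlation). Ccl22 was at 0.65, Ccl6 at 0.31, Egr2 at 0.67, Il7r at 0.59 and Il17rb, a receptor chain for interleukin 25, at 0.80. The fibroblast list had a median of 0.49 with 3 higher and 2 lower of 18 (camera adjusted p = 0.0179; adjusted p = 0.627 with an estimated correlation), with fibronectin, Fn1, at 0.90 and Inmt at −1.16. Heat shock genes had a median of 0.22 with 2 of 10 higher (camera adjusted p = 0.00151; adjusted p = 0.551 with an estimated correlation). Hsph1 was at 0.60 and Hspd1 at 0.27. Immediate early genes had a median of −0.31 with 4 of 16 lower (camera adjusted p = 0.00151; adjusted p = 0.551 with an estimated correlation). Ier3 was at −0.50 and Nr4a1 at −0.61. Mitochondrially encoded genes had a median of −0.19 with 0 of 13 (camera adjusted p = 0.00601; adjusted p = 0.627 with an estimated correlation), with mt-Nd2 at −0.37 and mt-Nd1 at −0.29. Of the fixed genes, Il5 was at −0.35 ± 0.47, Il13 at 0.36 ± 0.31, Il4 at 0.38 ± 0.32, Il33 at 0.20 ± 0.08, Ccl24 at 0.57 ± 0.49, Arg1 at 1.01 ± 0.61, Chil3 at 0.39 ± 0.13, Retnla at 0.09 ± 0.12, Muc5ac at −0.04 ± 0.14, Clca1 at −0.51 ± 0.18, Ccl11 at 0.01 ± 0.13, Calcb at −0.52 ± 0.39 and Jak1 at 0.21 ± 0.09.

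Lists that passed in none of the 3 comparisons are given by their medians for the chimera, intrathecal and subcutaneous comparison in turn. They were −0.00, 0.12 and −0.02 for alveolar type 2 cells, −0.05, 0.14 and 0.05 for alveolar macrophages, −0.26, 0.00 and −0.01 for epithelial alarmins and 0.02, 0.08 and −0.08 for smooth muscle and pericytes. They were 0.12, 0.47 and −0.58 for skeletal muscle, −0.03, 0.02 and −0.15 for neuropeptide receptors, −0.26, 0.01 and −0.06 for glucocorticoid targets and −0.39, 0.32 and −0.23 for erythroid cells and platelets. Trpv1, the RTX target, was at 0 to 0.317 CPM in every library, so lung RNA gave no measure of afferent loss.

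**Figure D3:**
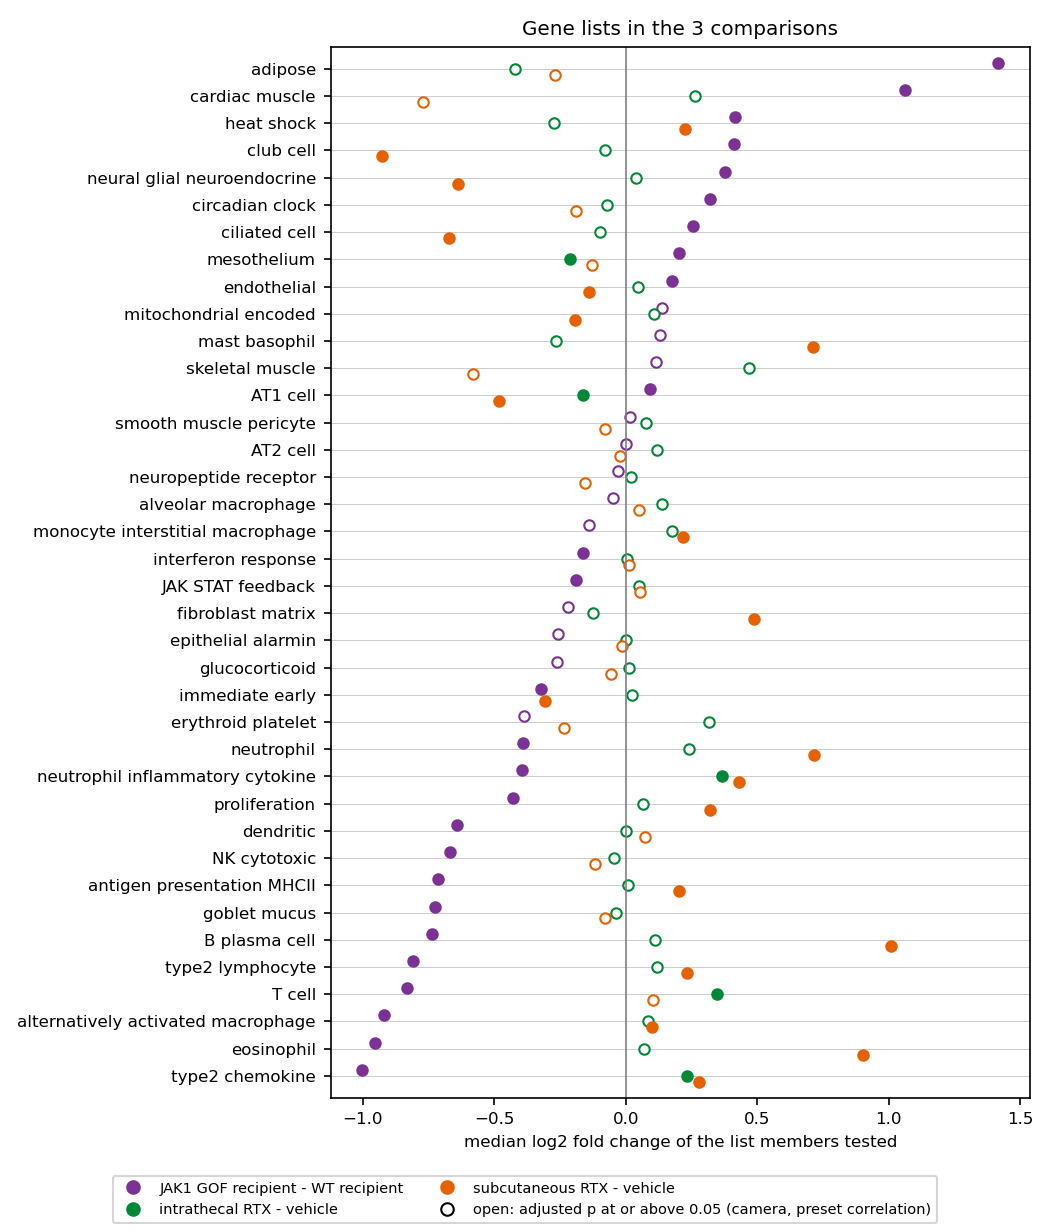
Median log2 fold change of the members tested of each of 38 gene lists (rows) in the chimera (purple), intrathecal (green) and subcutaneous (orange) comparison; filled points passed with camera at a preset correlation, and none passed with an estimated one. Most immune lists lie left of 0 in the chimera comparison and right of 0 in the subcutaneous one.

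The difference between the 2 RTX effects was tested directly, because an effect past the threshold in 1 experiment and not in the other does not show a difference. The effect of subcutaneous minus that of intrathecal RTX was −1.66 ± 0.23 for Hspb1 and −0.76 ± 0.10 for Hspe1 on the log2 scale. The endothelial genes Ly6c1, Ctla2a and Ecscr had differences of −0.97 ± 0.13, −0.81 ± 0.11 and −0.63 ± 0.09. Dnaja1, Syvn1 and Mtmr4 had positive differences of 1.02 ± 0.14, 1.02 ± 0.15 and 0.77 ± 0.11, and Cybb, a subunit of the phagocyte oxidase, one of 0.80 ± 0.10, with log2 fold changes of 0.75 after subcutaneous and −0.04 after intrathecal RTX. edgeR called 10 of 17972 genes, 5 higher and 5 lower, where scaling by total counts alone gave 8 and 5; 2735 genes had an unadjusted p under 0.05, and DESeq2 called 309 and limma voom 10. The count was 90 without subcutaneous RTX replicate 1, 59 without vehicle replicate 2 and 23 without RTX replicate 3, each with all 10 genes kept, 2 without subcutaneous RTX replicate 2 and 0 or 1 without subcutaneous vehicle replicate 1 or any 1 intrathecal library. The intrathecal side of this difference coincided with library state. On the subcutaneous side state was unbalanced, with state B only after vehicle and state A only after RTX. A fit of all 14 libraries called 0 genes by edgeR (2516 at an unadjusted p under 0.05), and with state as a term in it 6 genes were called, 2 of them among the 10.

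The recipient effect and the subcutaneous RTX effect ran opposite across genes. Over 16758 genes tested in both, Pearson's r of the log2 fold changes was −0.308 and Spearman's rho −0.413, across genes, which are not independent replicates. Of the 92 genes that fell in JAK1 GOF recipients and were tested in both, 83 had a positive log2 fold change after subcutaneous RTX, and of the 28 that rose 24 had a negative one. Among 711 genes with an unadjusted p under 0.05 in both comparisons, 34 had the same sign and 677 opposite signs, where independent lists give 181 and 179. The comparisons share no control libraries, but library state was unbalanced in both. State A was found only in WT recipient 1 in the chimera experiment and only after RTX in the subcutaneous one. Without WT recipient 1 the remaining chimera libraries were all of state B, and r was −0.215 and rho −0.451. The difference between the subcutaneous RTX effect and the recipient effect passed in 519 of 18074 genes by edgeR, 321 higher and 198 lower (400 and 146 when scaled by total counts alone), with 4054 genes at an unadjusted p under 0.05. That count was 1 without either GOF recipient, 3 without subcutaneous vehicle replicate 1, 62 without WT recipient 2, 134, 151 and 137 without subcutaneous RTX replicate 1, 2 and 3, 776 without WT recipient 1 and 1317 without subcutaneous vehicle replicate 2. The correlation was −0.144 without subcutaneous vehicle replicate 1 and −0.067 without the low-count filter. For the chimera and intrathecal comparison r was 0.024 and rho 0.028 over 16840 genes, with r at 0.141 without WT recipient 2, and for the 2 RTX comparisons r was −0.085 and rho 0.052 over 16911 genes.

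**Figure D4:**
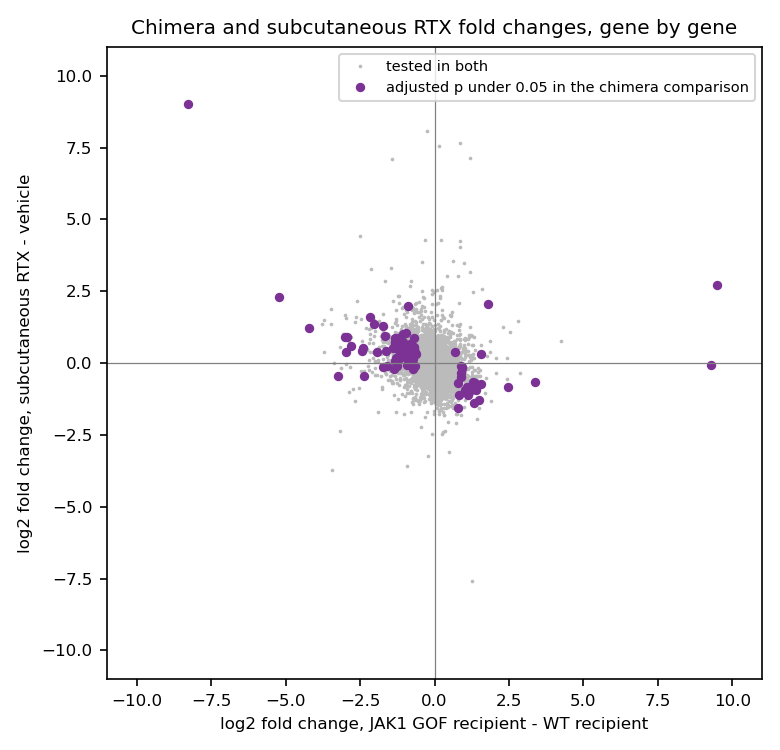
Log2 fold change of each of 16758 genes in the chimera comparison (horizontal axis) against the subcutaneous RTX comparison (vertical axis), with genes past the threshold in the chimera comparison in purple. Of the 92 purple genes left of 0, 83 lie above 0, and of the 28 right of 0, 24 lie below.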

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

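The differences between the RTX effects were planned; the tests of explanations in this part were chosen only after the results had been seen.

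The direct test of subcutaneous against intrathecal RTX picked out 10 genes. It also picked out 17 lists at the preset correlation, all lost otherwise (adjusted p = 0.708 to 0.846 with an estimated correlation, 0.388 or more with fry). The gene with the largest fitted difference was the noncoding RNA Gm38025 (10.02), a value that depends on the prior count because both subcutaneous vehicle libraries were at 0. Its counts were 21, 17 and 12 after subcutaneous RTX, at least 5.48-fold above a floor of 3 counts per library, and 12 and 10 after intrathecal vehicle against 2, 0 and 2 after intrathecal RTX. The others were Dnaja1 (1.02), Syvn1 (1.02), Cybb (0.80), Mtmr4 (0.77), Ecscr (−0.63), Hspe1 (−0.76), Ctla2a (−0.81), Ly6c1 (−0.97) and Hspb1 (−1.66), all at edgeR adjusted p-values of 0.0390 to 0.0422.

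At the preset correlation, lists with a higher median difference under subcutaneous RTX were mast cells and basophils (1.15), eosinophils (0.77), B and plasma cells (0.73), heat shock (0.68), neutrophils (0.46), fibroblasts (0.40), proliferation (0.24) and antigen presentation (0.17). Lower ones were skeletal muscle (−1.50), heart muscle (−1.13), club cells (−0.81), ciliated cells (−0.63), immediate early genes (−0.30), mitochondrially encoded genes (−0.29), alveolar type 1 cells (−0.28), alveolar type 2 cells (−0.20) and endothelium (−0.16). The number of lists was 8 without subcutaneous vehicle replicate 1 and 11 without subcutaneous RTX replicate 1.

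In the make-up of the intrathecal calls, the first pattern weighed, 8 of the 54 genes were among 41 trace genes picked from differences within the WT recipients and within the subcutaneous groups alone, where independent lists give 0.128 (one-sided Fisher's exact p = 4.50e-13). These include Rps3a2 and Hmga2, which set the states and were chosen with the intrathecal libraries in view. Without them 6 of 52 genes were among 39, against 0.117 (one-sided Fisher's exact p = 1.62e-09), so these calls may come from a library state shared with the other experiments, whose origin was not tested. The libraries contrasted to pick the trace genes followed the same states, and the test takes genes that vary together as independent. Its p-values are therefore no separate support. For the 5 called members of the heat shock list, a state term taken from the other experiments did not account for the whole difference. With state as a term the median ratio of their log2 fold changes to those without it was 1.46. In that fit 5 of 5 stayed more than 2 SE from 0, although Hspe1 went from 0.90 to 0.48 and only 2 kept the call. The term was set by the chimera and subcutaneous libraries alone, because state coincided with RTX here. Only the WT recipients held states A and B in the same group (recipient 1 and recipient 2), so the term rested on few libraries. The 5 genes were also picked by their intrathecal calls. A state effect within the intrathecal experiment was therefore not excluded. Whether intrathecal RTX or something else that set the RTX libraries apart changed the chaperones cannot be told apart, because 0 pairs of an intrathecal vehicle and an intrathecal RTX library shared a state (the explanation "RTX given intrathecally").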

How the results depend on the processing

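The fit with library state as a term was chosen after seeing the data; all other alternatives were planned. Against 124, 54, 0, 10 and 519 genes for the chimera, intrathecal, subcutaneous, route difference and subcutaneous against recipient difference, counts were 807, 655, 807, 147 and 2447 without the low-count filter, 290, 243, 683, 309 and 1363 with DESeq2, and 286, 123, 62, 47 and 1505 at an adjusted p of 0.1. With all 14 libraries in 1 fit they were 50, 7, 71, 0 and 1000 (the 0 by edgeR, beside 2516 genes at an unadjusted p under 0.05, and in the planned fit 309 by DESeq2 and 10 by limma voom). Without the robust prior the chimera and intrathecal counts were 79 and 34. With state as a term in the fit of all 14 libraries the counts were 177, 5, 184, 6 and 723. Of the planned calls 50 of 124, 4 of 54, 2 of 10 and 299 of 519 were kept, against 28, 7, 0 and 492 without the term. Leaving out 1 library gave 83 to 919, 19 to 40, 0 to 871, 0 to 90 and 1 to 1317. Beyond the higher threshold and fewer libraries, the cause was not tested.

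Lists past the threshold numbered 26, 5, 20 and 17 for the chimera, intrathecal, subcutaneous and route comparisons. Each became 0 with an estimated correlation and also with fry. The intrathecal number was 8 with DESeq2 size factors and 12 without the filter, and leaving out 1 library gave 20 to 28, 8 to 15, 15 to 26 and 8 to 20. The chimera and subcutaneous correlation was −0.067 without the filter and −0.449 over called genes alone, and −0.306 to −0.144 with 1 library left out; the 2 RTX comparisons had −0.682 over called genes and −0.159 to 0.020, and chimera and intrathecal −0.030 to 0.141. The cause was not tested.

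The labels number replicates in each group, but correlations of the deviations of same-numbered libraries across genes were negative in the RTX experiments (−0.310, −0.224, −0.143 and −0.116). With 2 controls centring makes each the mirror of a differently numbered pair, so these values established no pairs and the numbers were not taken as such. With a replicate block the counts were 123, 50, 0, 7 and 43, but only 87 of 124, 27 of 54, 1 of 10 and 21 of 519 planned calls were kept, and the intrathecal calls were 28 higher and 22 lower. edgeR's 0 stands beside 1930 subcutaneous genes at an unadjusted p under 0.05 in that fit, 683 genes by DESeq2 and 0 by limma voom in the planned one, and 10 intrathecal lists passed. Among followed genes past the threshold, 5 changed sign after intrathecal RTX with state as a term, besides 8 that had not passed: Ptn to 0.14, Cdkn2a to 0.45, Megf10 to −0.22, Cdk4 to 0.0464 and Arhgef25 to 0.0013. The sign held in every setting for 87 of 89 chimera, 34 of 53 intrathecal, 48 of 52 subcutaneous and 9 of 9 route genes, and the call held for 3 of 47 chimera, 0 of 29 intrathecal and 0 of 9 route genes.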

Other observations

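Of the tests in this part, only that of differences between libraries of 1 group was chosen before its result was seen; the others, and the genes singled out, were chosen after.

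Outside the naming rule, the genes that fell in JAK1 GOF recipients included Mmp12, the macrophage elastase, by 1.34, Itgax, the integrin CD11c, by 1.24, Ccr2, a chemokine receptor of monocytes, by 1.02, and Ptprc, the leukocyte antigen CD45, by 0.84. Further heart muscle genes rose, among them Tcap by 1.21, Fabp3 by 1.16, Tnni3 by 1.14 and Myl4 by 1.13, and so did Npr3, a natriuretic peptide receptor, by 1.02. Without GOF recipient 1 the calls of Itgax, Ccr2, Ptprc, Tcap, Fabp3, Tnni3 and Myl4 ended, without GOF recipient 2 those of Itgax, Ccr2 and Fabp3, and without WT recipient 2 that of Ptprc. Those of Mmp12 and Npr3 held whichever library was left out.

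After intrathecal RTX, single genes outside the naming rule included Herpud1, which fell by 0.85, Syvn1 by 0.57, Lum by 1.41, Hmcn1 by 0.89 and Igfbp5 by 0.64, with no test of a group behind them, and Ch25h, which makes 25-hydroxycholesterol and rose by 0.71. Cdk4, Os9 and Arhgef25, which fell by 0.56, 0.46 and 0.94, lie within 500 kb of each other on GRCm38 chromosome 10, and 2458 of 100000 random draws of 54 tested genes held as many in 1 window (permutation p = 0.0246). From the start of Cdk4 to that of Arhgef25 lay the starts of 8 tested genes, the 3 called ones included. These 3 and Lum also differed with library state elsewhere. Os9, Cdk4, Arhgef25 and Lum were at 393, 208, 76.7 and 28.2 CPM in subcutaneous RTX replicate 2 (state A) and 268, 117, 30.8 and 7.01 CPM in replicate 1 (state C). With state as a term in a fit of all 14 libraries Os9, Cdk4 and Arhgef25 were at −0.06, 0.0464 and 0.0013, so their grouping may follow library state. The calls of Os9 and Cdk4 ended without any 1 library, that of Syvn1 in each case but without vehicle replicate 1, and those of Herpud1 and Arhgef25 held in each case. Without RTX replicate 2 the calls of Lum, Hmcn1, Igfbp5 and Ch25h ended, without RTX replicate 1 those of Lum and Igfbp5, without vehicle replicate 1 that of Ch25h and without vehicle replicate 2 that of Igfbp5.

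A second pattern was the lower immune genes in JAK1 GOF recipients. Dilution by more heart muscle tissue is argued against as their sole cause, since it would lower other lung tissue alike. The 58 genes of alveolar type 1, alveolar type 2, endothelial and smooth muscle lists had a median of 0.0978 (interquartile range 0.283). Scaling holds typical genes near 0, so only the gap to the leukocyte genes below counts here. Endothelium and smooth muscle also occur in heart tissue, so the alveolar lists bear most on this. Other differences in the tissue taken were not tested. A lower leukocyte share of the sample is consistent with 20 pan-leukocyte genes, of which 20 were negative with a median of −0.542 (−0.84 to −0.12), a smaller fall than that of Chil3, although only 2 of the 20 passed the threshold and monocytes and interstitial macrophages, alveolar macrophages, and mast cells and basophils had medians of −0.14, −0.05 and 0.13. Fewer Xist-bearing cells cannot be told apart from this: Xist changed by −0.891 with the Y-linked genes at a median of −0.106, and the labels give no sex of donors or recipients. The JAK1 genotype of the recipients stays open as a biological explanation and is not separated from these by the 4 libraries.

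The last pattern was the opposite direction of the chimera and subcutaneous fold changes. Subcutaneous vehicle replicate 2 is argued against as its source, because without it the correlation was −0.30. Without subcutaneous vehicle replicate 1 the correlation was −0.144, so a contribution of that other vehicle library was not excluded. A common axis on which libraries of 1 group also differ may contribute: over 8 pairs of libraries within groups of the RTX experiments the median absolute r with the chimera fold changes was 0.130 (0.0046 to 0.229, the highest in the subcutaneous vehicle pair), between the levels set beforehand for and against, so this stays undecided. Library state was unbalanced in both comparisons as well, and its share in this pattern was not tested. An opposite effect of afferent loss and of JAK1 GOF stays open as a hypothesis, and was not tested further.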
